A study of Mus musculus with 5 samples.

How the data were processed

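Genomic DNA of 5 mouse mammary tumours and non-tumour DNA of the same mice was hybridised to 2-colour Agilent mouse CGH arrays, 1 array per mouse. Per the labels, the non-tumour DNA was labelled with Cy3 (green) and the tumour DNA with Cy5 (red) on every array, so the dyes were not swapped and a dye effect cannot be separated from a tumour effect shared by all arrays. The files recorded 1 scan day and 5 slides, 1 array per slide, so slide was not tested as a batch. Groups were taken from the tumour type in the labels: 3 glandular basal-like, 1 EMT/spindle and 1 mixed histology tumour. The label of the mixed tumour gives a heterozygous floxed Lfng genotype for the tumour channel, while its other channel and the design text name the conditional mutant. Replicate numbers only name the tumours. Each tumour came from its own mouse.

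Per the file headers, the authors used Agilent Feature Extraction 10.5.1.1, which subtracted the background, removed spatial trends and applied a linear dye normalization. The deposited intensity values per spot were the processed red and green signals, and the unprocessed median spot and background signals were also given. The deposited log10 ratio of red over green equalled the ratio of the processed signals within 0.0001 for at least 99.8% of the probes of every array. The authors' value table held that same log10 ratio in all 974016 cells of each array, with medians of 0.00789, 0.00351, 0.0137, 0.00687 and 0.00395 and the same direction. The genome build of the probe positions is not given in the sources used here. The deposited flags mark spots that are saturated, not well above background or outliers.

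The 6755 control spots of an array and between 161 and 3175 outlier spots were left out, spots of the same probe were averaged, and 504 probes on chromosome Y were left out, which left 962769 probes. The log2 ratio of the processed red over green signal was centred on the median of each array, with no loess or quantile step. By the scanner software's own limits, the spread of the mixed array and the red-channel reproducibility of the spindle array and of basal-like tumour 1 were out of range. The precision of each value is limited by the number of arrays.

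The planned tests were written for genes. Since the files carry no gene names, windows of 100 kb with at least 3 probes took their place, each valued by the mean of its probes. The rule fixed before the data were examined, of naming up to 10 called genes per direction with at most 1 per 2 Mb, was applied to windows. The reference gene table belongs to GRCm38, and array positions on chromosome 7 run past its last gene, so the builds differ. The table was used only for the order of genes and for the chromosome of each listed gene: 241 of 243 list entries matched. The copy number of Lfng, tests of gene lists and a correction for GC waves need an annotation or a genome of the array's build and were not run. The lists fixed in advance covered Lfng, the Met and caveolin neighbourhood (chosen by the study), the Notch pathway, receptor and PI3K signalling, mammary oncogenes, tumour suppressors, basal, luminal and mesenchymal markers, and antigen receptor genes as a sign of lymphocytes. The last was not used, as it needs gene positions.

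Windows were tested with limma 3.58.1 in R 4.3.3: an intercept over all 5 tumours, and a group-means fit for the basal-like mean and for the spindle and mixed tumours minus that mean. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 0.2. Simulated windows (24791) had the spread of the 3 basal-like tumours on all 5 arrays. There the fit over 5 tumours recovered 60 of 100 windows shifted by 0.5 and 85 of 100 shifted by 1, with 6 false calls. The basal-like fit recovered 22 and 56 of 100, with 2 false calls. Windows were drawn independently, and the 5 real tumours need not share the basal-like spread. The recovery and false calls of the fit over 5 tumours may therefore differ in the real data.

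Each chromosome of each array was segmented by penalised least squares (PELT, penalty 4 ln(n) times the probe variance, at least 10 probes per segment, probes limited to 4 SD around a running median of 11 probes), in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. Segments at 0.2 or more were called gained, at -0.2 or less lost, and those at 1 or more high-level. A chromosome was called when 80% of its covered length was gained or lost. In simulated arrays with 50-probe segments, all 100 planted at 0.6 and all 100 planted at 1 were recovered, and 31 of 100 planted at 0.3, so short segments near the calling threshold are missed. Recurrent regions were those where the mean of the 5 segment profiles, limited to 1.5 either way, exceeded the 95th percentile of the genome-wide maximum over 10000 random rotations of each profile along the autosomes, for gains and losses separately. In 1 simulated set of profiles, the test recovered all 100 points of a single planted region far above the background, with 0 other points called. A single set gives no rate of recovery or of false calls, and it held no probe effects shared between arrays. The common segment on chromosome 6 is the overlap of the runs of adjacent high-level segments of the 4 tumours that have them.

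The alternatives were normexp background correction on the median signals (the files hold no mean signal) with an offset of 50, the authors' value table, centring on the mode, only probes well above background in both channels (for windows and altered shares), the median over probes, other probe minimums, other effect minimums, a trended and robust variance, ratios minus the chromosome median, other penalties and thresholds, and leaving out each tumour. Windows of 50 and 500 kb, filters on the green channel alone and, for recurrent regions, the filter on both channels were added after the data had been seen.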

Results

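Array comparative genomic hybridisation was used to compare the DNA of 5 mouse mammary tumours with non-tumour DNA of the mouse that carried each tumour. The mice were on the FVB background and, per the labels, carried a conditional (floxed) Lfng allele with MMTV-Cre, a Cre recombinase driven in the mammary epithelium. Lfng encodes Lunatic fringe, a glycosyltransferase that modifies Notch receptors. The labels placed 3 tumours in a glandular basal-like group, 1 in an EMT/spindle group and 1 in a mixed histology group. The mixed tumour was also the tumour labelled as heterozygous for the floxed allele, so its genotype and its histology changed together. The study asked which copy-number changes the tumours had in common, and its title named an amplicon holding Met and the caveolin genes.

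Each array held 967261 probe spots, and positive log2 ratios stand for more DNA in the tumour. Between 0.428% and 1.07% of the probes of an array were not well above background in at least 1 channel. The spread between neighbouring probes, as the scanner software gave it, was 0.199 in basal-like tumour 3, 0.233 in basal-like tumour 2, 0.277 in basal-like tumour 1, 0.29 in the spindle tumour and 0.306 in the mixed tumour. The number of tumours, 3 in a single group and 1 in each of the others, limited the precision of every group value. The files named no genes and no genome build. Coordinates are therefore those printed on the arrays, no gene was placed inside a segment, and the copy number of Lfng itself was not analysed here.

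A high-level gain on chromosome 6 was shared by 4 of the 5 tumours, the 3 basal-like tumours and the spindle tumour. The segment common to all 4 ran from 17131585 to 18676627, a length of 1.55 Mb. Its mean log2 ratio was 3.78 in basal-like tumour 1, 5.08 in basal-like tumour 2 and 3.76 in basal-like tumour 3, and the group mean was 4.21 ± 0.76 (SD, n = 3), an 18.5-fold signal ratio. The spindle tumour had 3.90 in the same segment, 0.31 below the basal-like mean and within the spread of that group. The mixed tumour had -0.06, a signal ratio of 0.959. In the rotation test, which asks whether segments of the same sizes placed at random along the autosomes would overlap as much, this was the only recurrent gain, from 16122516 to 20317598. Its genome-wide permutation p was 0.0001, one-sided, the smallest that 10000 rotations can give. When tumours with a gain were counted instead, whatever its height, the chromosome 6 gain was not called, since 4 of 5 tumours did not exceed the threshold of 0.8 of the tumours.

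The gain had different borders in each tumour. In the spindle tumour it spanned the 1.55 Mb of the common segment itself, in 2 segments with means of 4.05 and 3.84. In basal-like tumour 2 it was a single segment of 3.20 Mb, from 16657334 to 19860770, with a mean of 5.07. In basal-like tumour 3 it was a single segment of 4.23 Mb, from 16094977 to 20325809, with a mean of 3.76, and it was the only high-level gain of that tumour. In basal-like tumour 1 it was a stepped block of 8.69 Mb and 13 segments, from 13203143 to 21893134, whose levels ran from 1.04 to 3.82 and peaked between 16210170 and 18340763, and 4 further high-level segments lay before it between 9947086 and 12401794, with means of 1.31, 2.23, 1.63 and 1.58. Met, a receptor tyrosine kinase, and Cav1 and Cav2, which encode coat proteins of caveolae, are neighbours on chromosome 6. In the GRCm38 gene table the order around them is Mdfic, Tfec, Tes, Cav2, Cav1, Met, Capza2, St7 and Wnt2. That table is not of the build of the array positions, so which of these genes the common segment held was not determined.

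**Figure D1:**
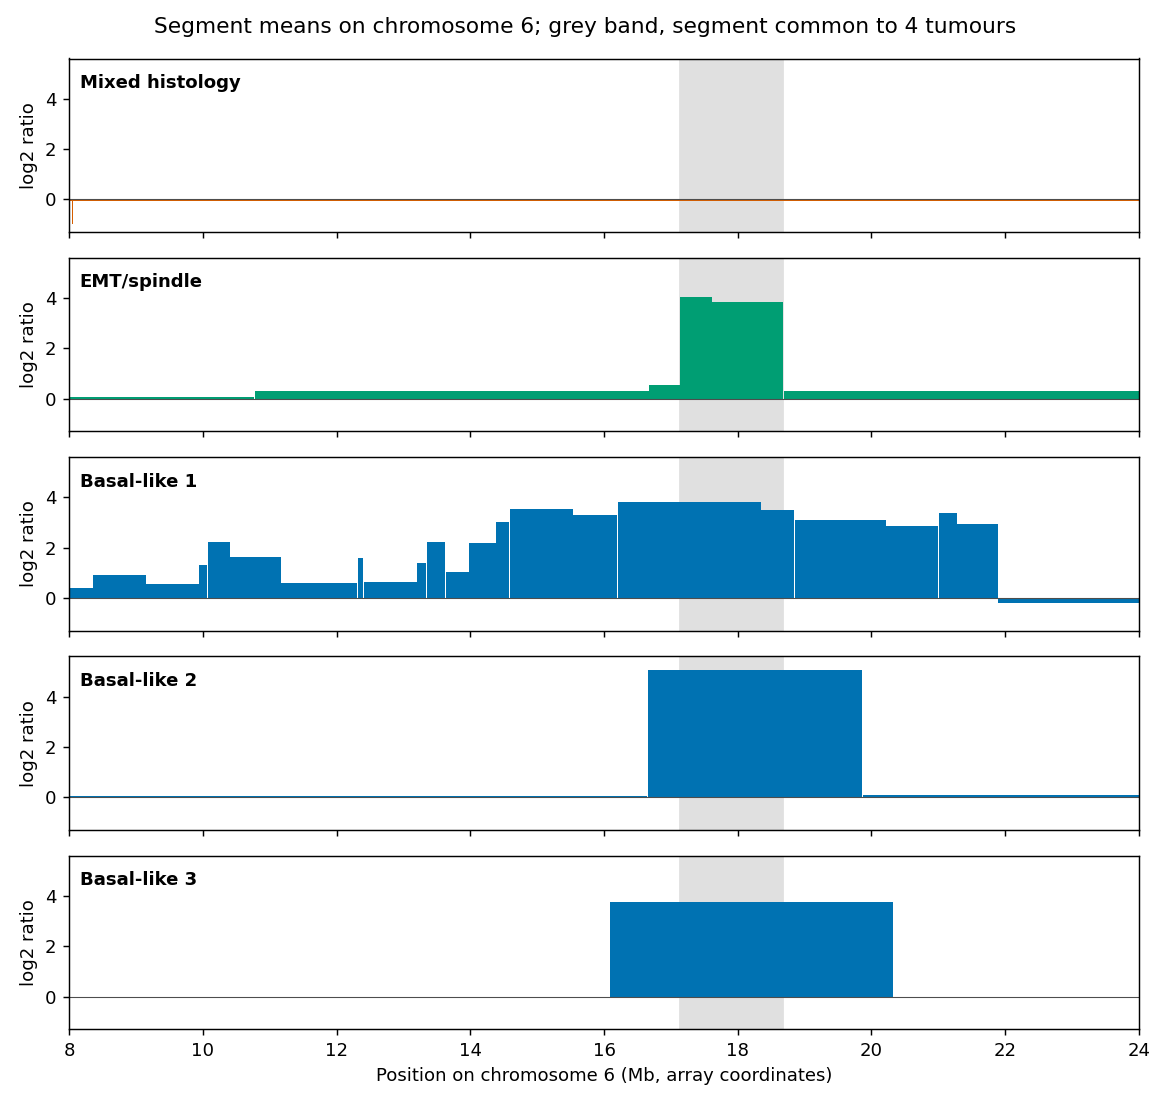
Segment mean log2 ratios (vertical axis, tumour over non-tumour DNA) along 8 to 24 Mb of chromosome 6 (horizontal axis) in each of the 5 tumours. The grey band marks the segment common to 4 tumours, where the basal-like and spindle tumours had means between 3.76 and 5.08 and the mixed tumour had -0.06.

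Across 100 kb windows, limma did not call the chromosome 6 gain in either replicated comparison. Of 24791 windows, 0 passed an adjusted p of 0.05 in the 3 basal-like tumours and 4376 had an unadjusted p under 0.05. The 14 windows inside the common segment had an adjusted p of 0.247 in that fit, equal to the lowest of any window, with 3 of 3 tumours higher. Over all 5 tumours, 0 windows were higher and 7 lower (4946 with an unadjusted p under 0.05), and the windows of the common segment had adjusted p between 0.0722 and 0.0785. Without the mixed tumour 12 windows were higher, all of them on chromosome 6.

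Chromosome 15 was the chromosome most often gained, with positive medians in 5 of 5 tumours. Its median log2 ratio was 0.48 in the spindle tumour, 0.28 in the mixed tumour, and 0.30 ± 0.11 (SD, n = 3) in the basal-like tumours. At least 80% of its length lay in gained segments in 4 tumours, and basal-like tumour 3 had a median of 0.18 with 0% of the length past the 0.2 threshold. The gene table places 15 genes of the lists fixed in advance on chromosome 15, fewer than the 25 on chromosome 11 or the 22 on chromosome 2. The 15 include 7 mammary oncogenes and insertion sites (such as Myc, a transcription factor of cell growth, and Wnt1, a secreted ligand). They also include the keratin genes Krt5 and Krt6a of the basal list, and Krt8 and Krt18 of the luminal list. The exact two-sided sign-flip p over the 5 tumours was 0.0625, the smallest that 5 tumours can give, and 0.312 after adjustment over 20 chromosomes. Chromosomes 7, 12 and 13 gave the same p, which 5 medians of the same sign reach whatever their size. In limma, no window of chromosome 15 passed (lowest adjusted p 0.0708), whereas 497 did with normexp background correction, 504 with the median over the probes of a window and 419 with a trended, robust variance.

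Whole-chromosome losses were seen on chromosomes 12 and 14 in several tumours. Chromosome 12 had medians of -0.75 in basal-like tumour 1, -0.30 in the spindle tumour and -0.21 in the mixed tumour, and was called lost in these 3. It had medians of -0.04 and -0.03 in basal-like tumours 2 and 3. Chromosome 14 was called lost in basal-like tumour 1, with a median of -0.79, and in the spindle tumour, with -0.30. Chromosome 12 carries Notch pathway genes of the lists fixed in advance (such as Jag2, Numb and Adam17). It also carries Mycn of the oncogene list and Akt1 of the receptor and PI3K list. Chromosome 14 carries 5 genes of the tumour suppressor list (Rb1, Fhit, Pbrm1, Bap1 and Lats2). Chromosomes 8 and 11 carry 6 and 5 of that list. Chromosome 1 carries Psen2 and Ncstn, subunits of the protease that cleaves Notch, Mdm4, a p53 inhibitor, and Casp8 of the tumour suppressor list. No link between the listed genes and these changes was tested. Chromosome 1 was gained in basal-like tumours 1 and 2. Its medians were 0.47 and 0.29 there, 0.17 in basal-like tumour 3 and 0.22 in the spindle tumour, against -0.06 in the mixed tumour.

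Over all tumours, 9 whole-chromosome gains and 10 losses were called. The mixed tumour gained chromosomes 3 and 15 and lost chromosomes 8, 10, 12, 13 and X. The spindle tumour gained chromosomes 2 and 15 and lost chromosomes 7, 12 and 14. Basal-like tumour 1 gained chromosomes 1, 15 and 19 and lost chromosomes 12 and 14, basal-like tumour 2 gained chromosomes 1 and 15, and basal-like tumour 3 had no call. At a threshold of 0.3 the calls fell to 4 gains and 4 losses.

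**Figure D2:**
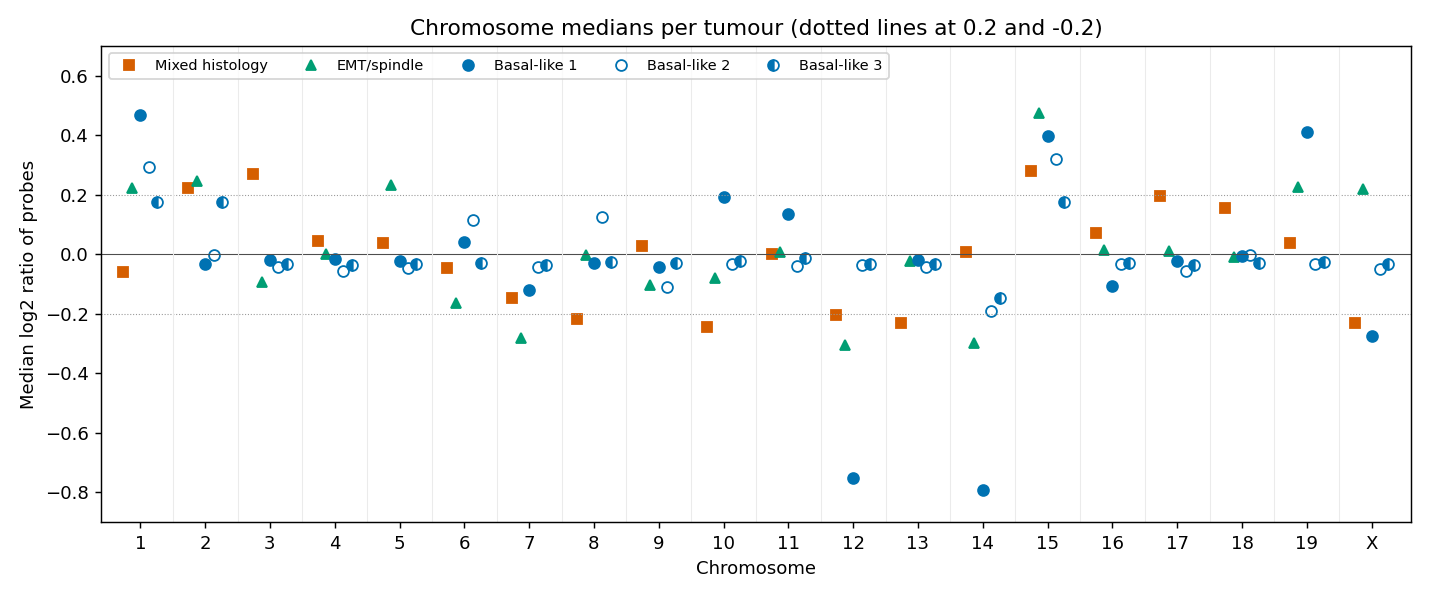
Median log2 ratio of the probes of each chromosome (vertical axis) by chromosome (horizontal axis), 1 symbol per tumour. Chromosome 15 lay above 0 in all 5 tumours, between 0.18 and 0.48, and chromosomes 12 and 14 reached -0.75 and -0.79 in basal-like tumour 1.

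The basal-like tumours differed widely in how much of the genome passed the calling threshold of 0.2. Gained and lost segments covered 40.9% of the probe-covered length in basal-like tumour 1, 13.6% in basal-like tumour 2 and 3.87% in basal-like tumour 3, a mean of 19.5% ± 19.2 (SD, n = 3). Without basal-like tumour 1 the mean was 8.75%. The spindle tumour had 52.9% (26.9% gained and 26.0% lost) and the mixed tumour 41.2% (13.8% gained and 27.5% lost). No test was run between 3 tumours and 1. The share counts length past a fixed log2 ratio, so it also depends on the size of the ratios. In basal-like tumour 3 the medians of chromosomes 1, 2 and 15 (0.17, 0.18 and 0.18) lay just under 0.2. Basal-like tumour 1, the spindle tumour and the mixed tumour had the largest shares and also the widest spread between neighbouring probes. The order of the tumours depended on the threshold: at 0.3 the altered share was 37.2% in basal-like tumour 1, 24.7% in the spindle tumour, 4.58% and 2.33% in basal-like tumours 2 and 3, and 3.42% in the mixed tumour, and at 0.15 the shares in the same order were 47.3%, 57.3%, 14.4%, 14.5% and 52.5%. With centring on the mode in place of the median, the mixed tumour had 3.13% gained and 30.7% lost.

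**Figure D3:**
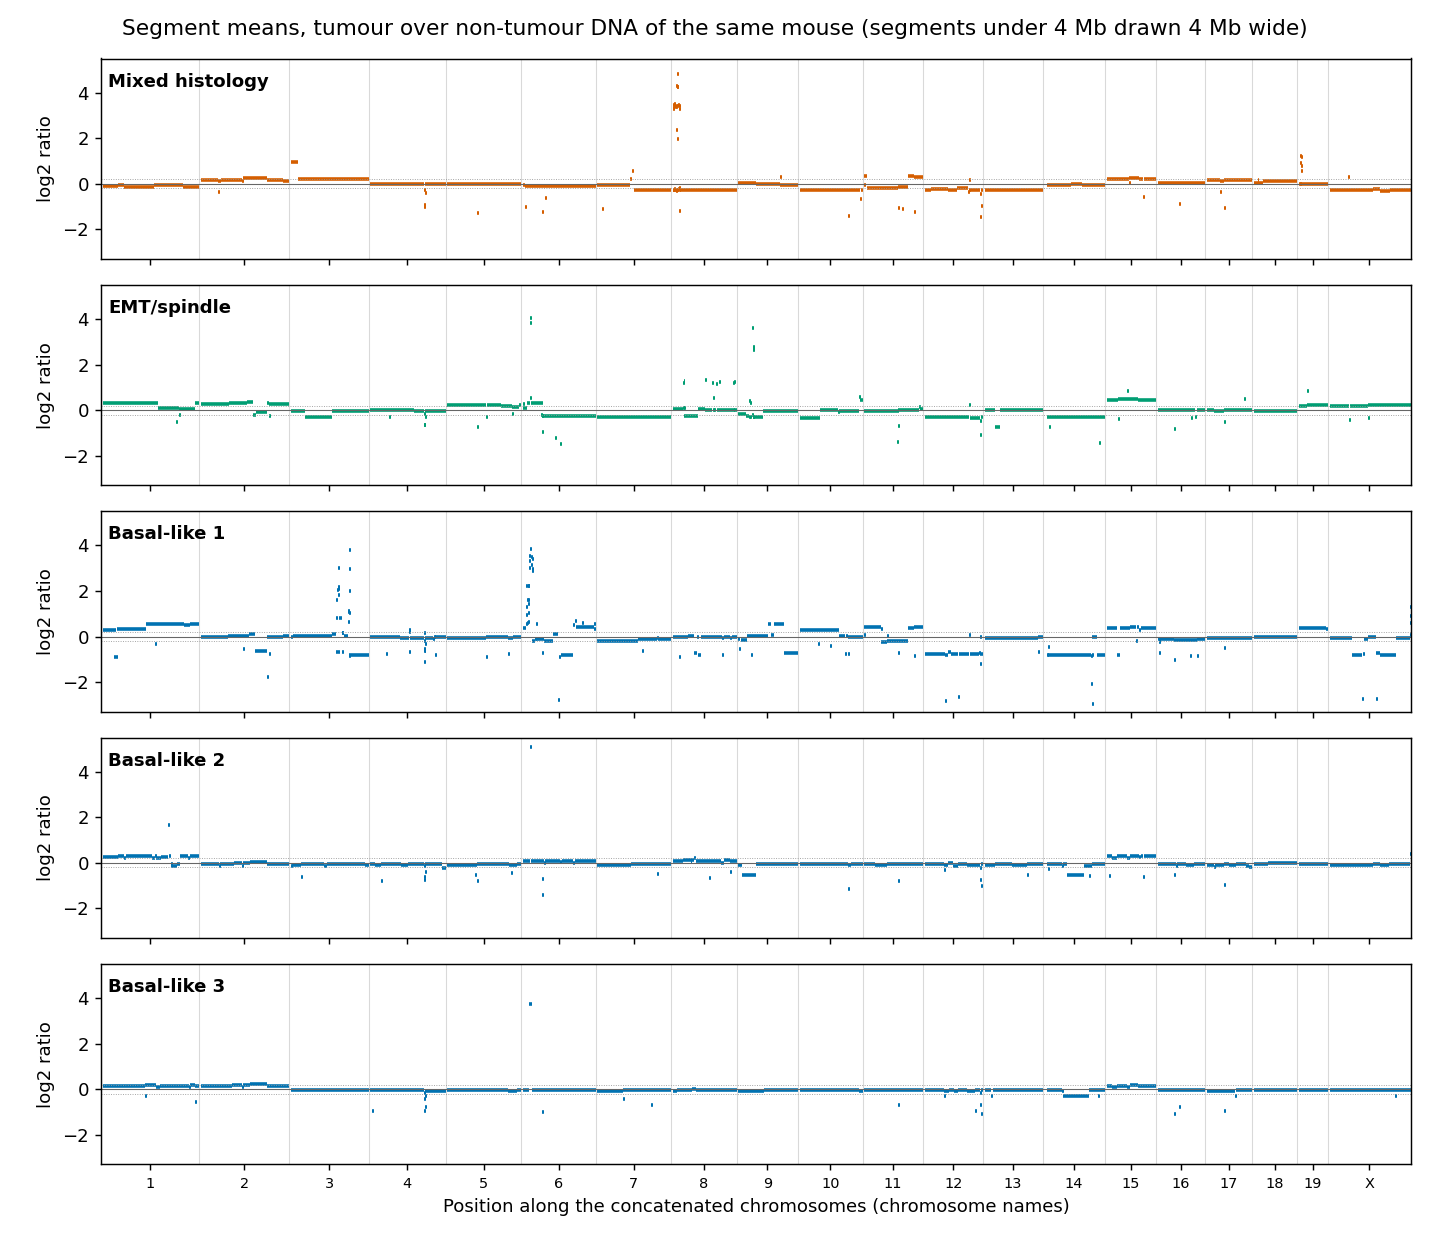
Segment mean log2 ratios (vertical axis) along chromosomes 1 to 19 and X (horizontal axis) in each tumour, with segments under 4 Mb drawn 4 Mb wide and dotted lines at 0.2 and -0.2. The 4 tumours with the chromosome 6 gain have their highest segment there, with means between 3.76 and 5.07, and the mixed tumour shows its highest points, up to 4.83, on chromosome 8.

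Basal-like tumour 1 carried further high-level gains and deep losses that were called in no other tumour. On chromosome 3 it had 12 high-level segments between 94381600 and 119905563, with a mean of 2.99 at 98435312 to 98766533 and 3.78 at 119476863 to 119519387. Its 5 deepest losses of more than 80 probes were at 43450339 to 44050821 of chromosome 12 (-2.85), 74166164 to 76559774 of chromosome 6 (-2.77), 69489318 to 69784182 of chromosome X (-2.76), 97286650 to 97644947 of chromosome X (-2.73) and 71029869 to 71599625 of chromosome 12 (-2.64). Over 97% of the probes in each of these were well above background in the non-tumour channel. In basal-like tumour 2 the only high-level gain besides chromosome 6 was at 134307793 to 135171325 of chromosome 1, with a mean of 1.67 over 460 probes.

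The spindle tumour was compared with the basal-like group, which describes that 1 tumour and not its type. No window passed in limma (0 of 24791, with 3376 at an unadjusted p under 0.05 and a lowest adjusted p of 0.334), a contrast that assumes the single tumour varies like the other 3. Its high-level gains outside chromosome 6 lay at 30367598 to 31319660 of chromosome 9, with a mean of 3.61, in 3 smaller segments of chromosome 9 up to 33826476, and in 8 short segments of chromosome 8 between 24180503 and 125653811, all at levels from 1.17 to 1.33. A deep loss at 69359518 to 69436596 of chromosome 11 had a mean of -1.39 over 47 probes, and losses of the same order lay at 78270051 to 78427737 of chromosome 6 (-1.49) and at 112341516 to 112459840 of chromosome 14 (-1.45).

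The mixed tumour carried high-level gains in the first part of chromosome 8 that were called in no basal-like tumour. Of 24791 windows, 28 were higher and 0 lower than the basal-like mean by limma (4011 at an unadjusted p under 0.05), all 28 on chromosome 8. This contrast describes 1 tumour, takes its spread from the 3 basal-like tumours alone, and gave 0 windows when any 1 of them was left out, with a trended, robust variance and with 500 kb windows. The largest difference was 4.83 (SE 0.13, adjusted p = 0.0268) at 11100001 to 11200000, where the mixed tumour had 4.84 and the basal-like tumours 0.01 ± 0.12 (SD, n = 3). Windows starting at 5500001, 7800001, 3200001 and 14500001 differed by 3.52, 3.48, 3.33 and 2.69. The gain was made of 18 high-level segments, which together covered 3.67 Mb of the 11.5 Mb between 3104116 and 14639074 and had means from 1.96 to 4.83. The 11 segments between them (several of the 18 are adjacent) were at the level of the rest of the chromosome, from -0.31 to -0.18. Of the high-level segments, the lowest (1.96, SE 0.61, and 2.36, SE 0.53) held only the minimum of 10 probes each. The others ran from 3.28 to 4.83. The mixed tumour also had 0.96 over the first 13.9 Mb of chromosome 3 (3000029 to 16936162) and 2 high-level segments on chromosome 19, with means of 1.22 and 1.19. On chromosome 6, where it lacked the gain, 0% of its 753 probes in the common segment had a log2 ratio above 1, against at least 99.86% in each of the other 4 tumours. Mixed minus basal-like was -4.27 in that segment, where the basal-like SD was 0.76. The contrast called no window there, so windows it did not call can still differ widely.

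**Figure D4:**
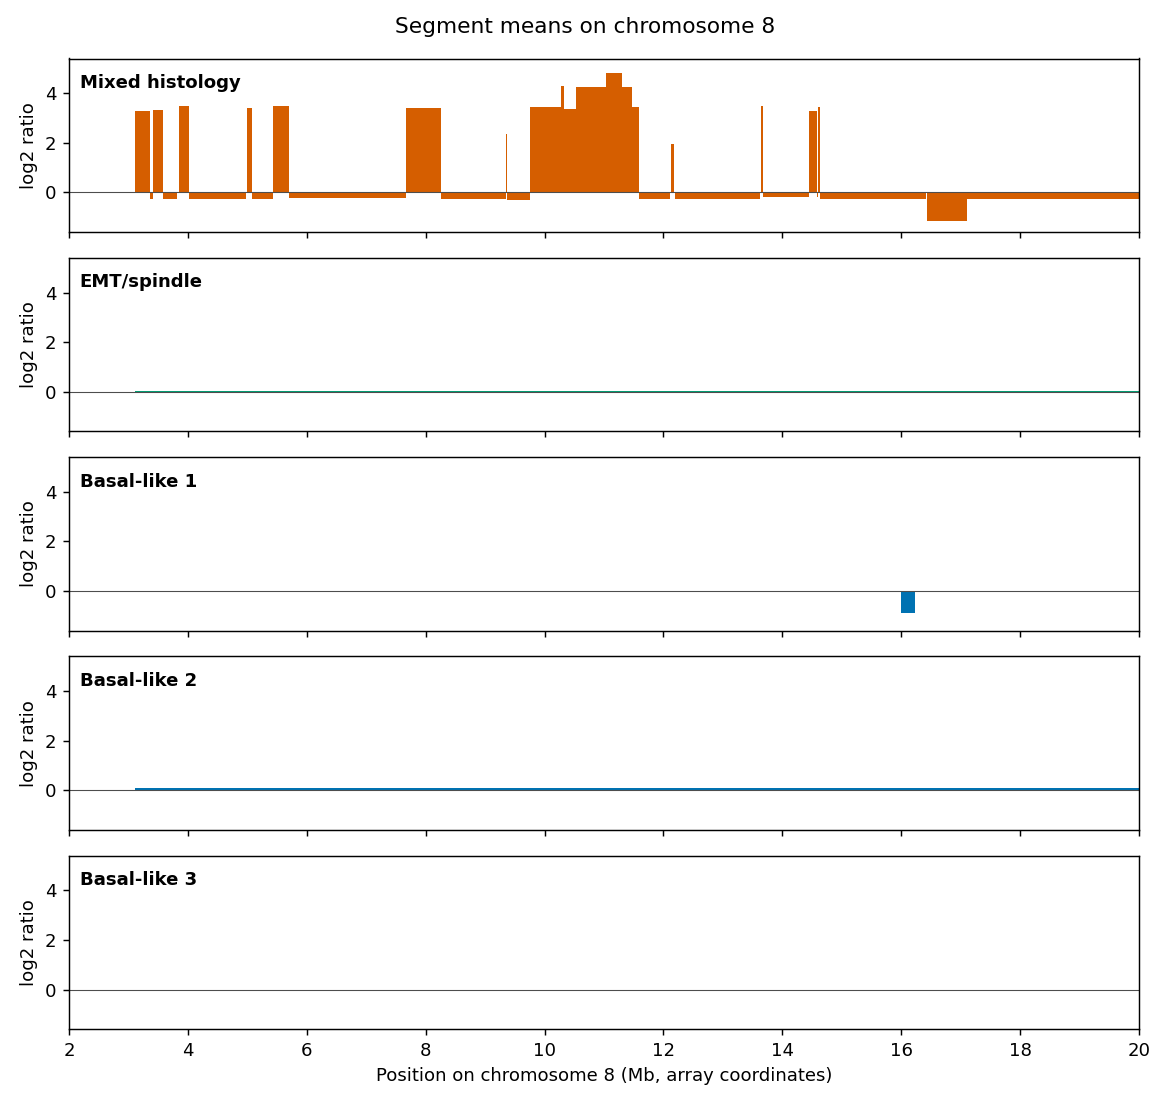
Segment mean log2 ratios (vertical axis) along 2 to 20 Mb of chromosome 8 (horizontal axis) in each tumour. The mixed tumour shows 18 high-level segments with means from 1.96 to 4.83, some of them adjacent and the others parted by 11 segments between -0.31 and -0.18, and the other tumours show none there. The lowest means, 1.96 and 2.36, rest on the minimum of 10 probes each.

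Short segments lower in the tumour than in the non-tumour DNA recurred at 10 places. They lay on chromosomes 4 (2 segments), 5, 6, 10, 11, 12 (2 segments), 16 and 17, with negative means in 5 of 5 tumours. Their genome-wide permutation p in the rotation test lay between 0.0001, the smallest possible, and 0.0259 (one-sided). Each array was rotated by its own offset, so a property of the probes, which all arrays share, would recur as well. The p therefore does not tell loss in the tumours from such a property. The longest segments were at 111752907 to 112238928 and 112679080 to 113216078 of chromosome 4. The first of these had a mean of -1.02 in the mixed tumour, -0.64 in the spindle tumour and -0.56, -0.71 and -0.93 in the basal-like tumours. The 7 windows that limma called lower over all 5 tumours lay on chromosomes 4, 6, 11, 12 and 14, with mean log2 ratios from -0.95 to -0.55 and adjusted p from 0.0338 to 0.0388. The window starting at 112100001 of chromosome 4 had -0.95 (SE 0.07), and those at 41000001 of chromosome 6, 105100001 and 115300001 of chromosome 12, 71000001 of chromosome 11 and 44500001 of chromosome 14 had -0.84, -0.78, -0.67, -0.77 and -0.55. The call was not stable: 0 windows were lower without the spindle tumour, without basal-like tumour 2 or 3, with a trended, robust variance, minus the chromosome median and with 50 kb windows, 3 without the mixed tumour and 23 without basal-like tumour 1. The probes of the 10 segments were dim: the median non-tumour signal of a segment was -4.41 to -3.28 log2 units relative to the median of the array, and 0% to 37.5% were well above background there. With only probes bright in both channels, 0 recurrent losses and 0 lower windows were called, and with a filter on the non-tumour channel alone 2 recurrent losses and 0 windows were. These filters cannot decide whether the segments are low. In those of chromosomes 5, 10 and 16, 0% of the probes were bright in the non-tumour channel, so their own probes could not give a call. The filter on both channels also drops probes for a low tumour signal.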

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

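Of the tests in this part, those of dye bias and of genotype on chromosome 6, of failed probes on chromosome 8, and of probes grouped by brightness were chosen after the result was seen. Groups of 3 or fewer tumours were not searched for outlying samples.

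Chromosome 8 drew attention because 28 windows were higher in the mixed tumour than in the basal-like group by limma. With 1 mixed tumour this describes that tumour and not its type, and 0 windows passed when any basal-like tumour was left out, with a trended, robust variance or with 500 kb windows. The gain there alternates between high-level segments and segments at the level of the rest of the chromosome. Over-segmentation of a noisy array was tested with the stricter penalty of 8 ln(n), under which the number of high-level segments was 18, the same as in the main setting. This count cannot decide, because the steps between high-level segments and the others were too large for that penalty to merge them. Such steps were far above the probe noise SD of 0.30 in this array. Failed probes inside 1 amplified block were also tested: the 2754 probes between the high-level segments had a mean log2 ratio of -0.26, and 0.871% of them were not well above background in the non-tumour channel. These probe values argue against failed probes. A candidate explanation is amplification of separate pieces of the chromosome in this tumour, found and tested on the same array. Whether it goes with the mixed histology or the heterozygous Lfng label is open, since there was 1 such tumour.

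The chromosome 6 gain was present in 4 of 5 tumours. A probe or dye bias shared by all arrays would also appear in the mixed tumour, which was hybridised with the same dyes and had -0.060 in the common segment. Chance overlap of unrelated gains was tested by rotation, with a genome-wide permutation p of 0.0001, the smallest possible, though the count of tumours with a gain, which ignores its height, called 0 recurrent gains. The first value argues against a shared bias and the rotation p against chance overlap of gains this high. The Lfng genotype or histology of the tumour without the gain cannot be told apart from chance absence, because the number of arrays of that genotype and histology was 1.

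The 10 short segments lower in all 5 tumours lay on probes with little non-tumour signal. If little target DNA in both channels were the cause, as where the mice lack a sequence that the array carries, other dim probes would be as low. The 11437 of them had a mean of 0.10 in the spindle tumour and from -0.34 to -0.13 in the others. At matched brightness, the 176 inside probes that lay 1 to 4 log2 units under the array median were compared with outside probes in 3 classes. On the 5 arrays they were lower by 0.47 to 0.95 in each class (inside minus outside -0.467 at the least, SE at most 0.13). These gaps cannot decide on dimness, because picking the segments as low on the same arrays widens them. Most outside probes of the 3 classes together were also well above background in the non-tumour channel. They need not carry the ratio of probes without target DNA. Dimness also stays open for the 191 of 380 probes more than 4 units under the median. Outside probes of that class had means of -0.74 in the mixed tumour, -0.23 in the spindle tumour and -0.15, -0.52 and -0.55 in the basal-like tumours. Inside probes lay lower by 0.28 to 0.33 on 4 arrays but by 0.08 (-0.0842, SE 0.0777) in basal-like tumour 2. DNA lost in the tumours would lower probes of ordinary brightness, and the 13 such probes inside the segments had means from -0.56 to -0.41 on the 5 arrays, but these segments were picked as low on the same arrays and the probes are few. Loss, little target DNA in both channels and, as dyes were never swapped, a dye effect specific to these sequences cannot be told apart here. Whether the segments vary in copy number between strains was not tested.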

How the results depend on the processing

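Across 215 alternative values of 16 results, 176 stayed within the main result's spread or within 1.5 times its count. Many of the 176 were counts of 0 that stayed 0, which shows no stability of a finding. The altered shares of the single spindle and mixed tumours were judged by the basal-like SD of 19.2. This SD lets large shifts pass: without basal-like tumour 1 the basal-like mean fell from 19.5% to 8.75% and stayed within it. The settings with windows of 50 and 500 kb, with probes bright in the green channel and, for recurrent regions, with probes bright in both channels were chosen after seeing the data. The basal-like mean of the chromosome 6 segment was 4.21 and ran from 3.77 (without basal-like tumour 2) to 4.43 (normexp) in the alternatives. Each shift was under the SD of 0.76, a limit that leaving out 1 of 3 tumours cannot exceed. Over all 5 tumours, 0 windows were higher in the main fit, against 503 with normexp, 508 with the median over probes and 422 with a trended, robust variance, nearly all on chromosome 15, and between 0 and 12 when a tumour was left out. The 7 lower windows became 23 with normexp, 26 with the median over probes, 11 with at least 1 probe, 1 with 500 kb windows, and 0 with bright probes, with green bright probes, with a trended, robust variance, minus the chromosome median and with 50 kb windows. They numbered between 0 and 23 when a tumour was left out. In the basal-like tumours, 1 window of 500 kb was higher against 0 of 100 kb. The 28 windows higher in the mixed tumour became 139 minus the chromosome median (with 5 lower against 0), 68 with 50 kb windows, 0 with 500 kb windows, 0 with a trended, robust variance and 0 when any basal-like tumour was left out. At a calling threshold of 0.3 the altered share was 24.7% in the spindle tumour and 3.42% in the mixed tumour. Whole-chromosome gains numbered 15 at a threshold of 0.15, 4 at 0.3 and 14 at 60% of the length, against 9, and losses 4 at 0.3, against 10. Recurrent gains numbered 0 by the count of tumours, which did not call chromosome 6, against 1. With the penalty of 2 ln(n) they numbered 2, both inside the chromosome 6 region of the main setting. Recurrent losses numbered 6 in the basal-like tumours alone, 2 with green bright probes and 0 with bright probes, against 10. The cause of these shifts was not tested, apart from the smaller number of probes or tumours that some settings leave. No paired analysis was possible because each array already sets a tumour against its own mouse and the replicate numbers pair no arrays. Alternatives for Lfng, for gene lists and for GC waves were not run. Signal over background limited the dim segments, where at most 37.5% of probes were well above it.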

Other observations

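Losses on chromosome 14 overlapped in 4 of 5 tumours, an overlap noticed after the data had been seen. The overlap of the longest lost segments ran from 48928020 to 82778701, a length of 33.9 Mb, and had means of -0.82, -0.54 and -0.30 in the basal-like tumours, -0.31 in the spindle tumour and -0.02 in the mixed tumour. The basal-like mean was -0.55 ± 0.26 (SD, n = 3). The mean over the 5 tumours was -0.40, short of the size of 0.559 that the rotation test needed for a recurrent loss, so this overlap did not pass. The same 4 tumours carried the chromosome 6 gain, and the association was not tested, as only 1 tumour lacked both.

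The size of whole-chromosome changes differed between tumours. In basal-like tumour 1 chromosome 15 stood at 0.40 and chromosome 14 at -0.79, in the spindle tumour at 0.48 and -0.30, and in the mixed tumour chromosomes 3 and 13 stood at 0.27 and -0.23. Chromosome 9 was lost in part in basal-like tumour 2 (10304288 to 39036324, mean -0.55) and in basal-like tumour 1 (95895168 to 124061581, mean -0.74, 5352497 to 8605696, mean -0.55, and 28184403 to 28379108, mean -0.80). The spindle tumour had losses there too, the longest at 33835109 to 52652695 with a mean of -0.30. The spindle tumour had a loss on chromosome 13 (24191635 to 33591371) with a mean of -0.72.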
